A study of Mus musculus with 12 samples.

How the data were processed

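The 12 libraries came from mouse OPCs exposed for 4 h to vehicle, CPC, AEBDAC or MTOAC, 3 libraries per group, and the group of each library was taken from its treatment label. Per the labels' protocols, poly(A) RNA was purified, made into libraries with a kit that is not described as marking strand, and sequenced on a NovaSeq as 150 bp paired reads with at least 20 M reads per library. Per the submitters' processing notes, Salmon was used and the genome build was mm10; the version of Salmon and the annotation are not given in the sources used here. The authors deposited 1 table per library with TPM values for 35385 gene symbols. TPM are scaled within each library to the sum over all transcripts, so a rise of a few abundant transcripts lowers the values of all others, and they keep no trace of the depth, which is unknown here beyond the stated minimum. The deposited totals lay between 772637 and 797758 TPM. Actb and Eef1a1, which most cells express strongly, were listed at only 31.6 to 76.2 and 34.0 to 63.2 TPM. The cause was not tested, and no value was recomputed from reads. Of the symbols, 34858 were matched to GENCODE release M21 on GRCm38, the assembly of mm10, from which coordinates were taken.

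The test was limma 3.58.1 in R 4.3.3 with trend and robust empirical Bayes moderation on log2(TPM + 1), so fold changes are on that scale and understate the change of low genes. Genes with at least 1 TPM in at least 3 libraries were tested, 12009 in all, and a symbol below this filter was not tested. All 12 libraries entered 1 fit with 4 group means, which share 1 estimate of the spread, and no covariate; p-values are two-sided and were adjusted by Benjamini and Hochberg within a comparison, with calls at an adjusted p under 0.05. An exact permutation test of 3 against 3 libraries cannot go below 0.1. The half-width of the 95% interval of the median gene was 0.55 log2. Because the median gene shifted between groups, list medians are given relative to the median of all tested genes, and fold changes of single genes as fitted unless stated. The planned design provided for counts or TPM, and the TPM branch was used.

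Before the data were examined, 24 gene lists were fixed: targets of the integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, fatty acid synthesis, LXR targets, OPC markers, myelin and differentiation genes, markers of astrocytes, neurons, microglia, pluripotent cells and mesenchymal cells, cell cycle, p53 targets, NRF2 targets, heat shock, immediate early genes, apoptosis, inflammatory genes, mitochondrially encoded genes, nuclear oxidative phosphorylation, glycolysis and hypoxia, lysosome and autophagy, and ribosomal proteins. A list needed 3 tested members, which left 22. Lists were compared with the other genes by camera in limma with a preset correlation of 0.01, adjusted over the 22 lists of a comparison. The same test with an estimated correlation was run beside it and called 0 lists in each of the 6 comparisons. At the preset correlation other splits of the 6 libraries of a comparison called as many lists. The number of lists called therefore does not set the real grouping apart. The genes to name were also fixed before the data were examined: for each compound against vehicle the 6 highest and 6 lowest fold changes among called genes with a mean of at least 5 TPM in the higher group, non-overlapping libraries and a named gene model; 24 fixed genes; and the 3 members of each list with the smallest p. Between compounds 4 per direction were to be taken. Genes named outside this rule are said to be so, and some genes the rule names are not reported here. The fixed genes Atf3 and Myrf were below the filter.

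No pair of libraries held identical values, and correlations across genes within a group lay between 0.915 and 0.964. The replicate numbers come from the sample titles, which do not say that a number marks a shared culture. Whether the numbers pair the libraries was decided by correlating, across genes, the deviations of same-numbered libraries from their group means, with pairing where all 3 correlations were over 0.1. They were 0.34, 0.31 and 0.23 for CPC and vehicle, 0.28, 0.42 and 0.23 for AEBDAC and CPC, and 0.33, 0.36 and 0.30 for MTOAC and AEBDAC, so that by this rule the numbers paired the libraries in these 3 comparisons and the other 3 did not meet it. Blocked values are given beside results in these comparisons where they change a call. As these 3 link the numbers of all 4 groups, a pairing in the other 3 stays open.

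The test was tested on simulated data built on the 12009 genes. Their noise was normal and independent between genes and libraries, with no effect of the replicate number. Only genes with a mean log2(TPM + 1) over 2 were changed, so the rates below do not cover lower genes. With 100 genes changed by 1 log2, 47%, 62% and 54% were called for CPC, AEBDAC and MTOAC against vehicle, and with 100 changed by 2 log2 91%, 90% and 92%, with 6, 5 and 7 false calls. Alternatives were quantile normalization of the log2 values, no filter on low values, limma without trend and robust fitting, a pseudocount of 0.1, a fit of only the groups compared, the replicate number as a block, leaving out each library in turn, a minimum absolute fold change of 1 log2, and camera with an estimated correlation. Chosen after the data were seen were quantile normalization combined with the block, with leaving out vehicle library 1 and with the estimated correlation. Genes with a near-identical copy or an overlapping gene are reported as uncertain, since the labels do not say that strand was used.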

Results

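Gene expression was measured by poly(A) RNA sequencing in mouse oligodendrocyte progenitor cells (OPCs), the precursors of the myelin-forming cells of the central nervous system, derived from pluripotent stem cells. The cells had attached for 1 h in medium that permits differentiation and were then exposed for 4 h to a vehicle, dimethyl sulfoxide, or to 1 of 3 quaternary ammonium compounds. Cetylpyridinium chloride (CPC) is a pyridinium ring with a hexadecyl chain. C12-C14-alkyl(ethylbenzyl)dimethylammonium chloride (AEBDAC) carries an ethylbenzyl ring and an alkyl chain. Methyltrioctylammonium chloride (MTOAC) carries octyl chains and no aromatic ring. Each compound was used at its own IC75, a concentration inhibiting by 75%, so the doses differed between compounds, and the concentrations themselves are not given in the labels. Each of the 4 groups had 3 libraries, numbered 1 to 3. The labels do not say that these came from separate cultures, so the p-values measure the spread between these libraries. The deposited values were length-scaled transcript abundances (TPM) for 35385 gene symbols, summing to between 772637 and 797758 per library, with 15431 to 16210 symbols above 0. TPM keep no depth, so the depth of each library is unknown beyond the stated minimum of 20 M reads. The series asks how such chemicals affect the development of oligodendrocytes.

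Olig1 and Olig2, transcription factors of the oligodendrocyte lineage, stood in vehicle at 1194 ± 154 TPM and 459 ± 96.3 TPM (SD, n = 3), and Pdgfra, the growth factor receptor that marks OPCs, at 31.4 ± 3.62 TPM. Of genes listed for myelin and differentiation, Mbp, which encodes a major myelin protein, stood at 2.76 ± 2.37 TPM, Cnp at 53 ± 6.10 TPM and Fyn at 316 ± 22.5 TPM. Of the 12 microglial and myeloid markers none was tested, and of the 10 pluripotency markers 2 were, Esrrb and Klf2, neither of which was called in any comparison. Vehicle library 1 stood apart from the other 11 libraries. The mitochondrial gene mt-Nd3 was listed at 0 in it and at 8716 to 13261 TPM in the others, and its mitochondrially encoded genes summed to 86422 TPM against 147539 to 183001 TPM. Not all of them were low in it: mt-Co2 stood at 8872 TPM against 2786 to 5293 TPM, and mt-Co1, mt-Co3 and mt-Nd5 lay within the range of the others. Its mean correlation with the other libraries across genes was 0.917, against 0.935 to 0.957 for the others, where genes are not independent replicates. Counts of called genes against vehicle are therefore also given without it. It also entered the shared spread of the comparisons between compounds, where only the fits of the 2 groups alone leave it out.

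**Figure D1:**
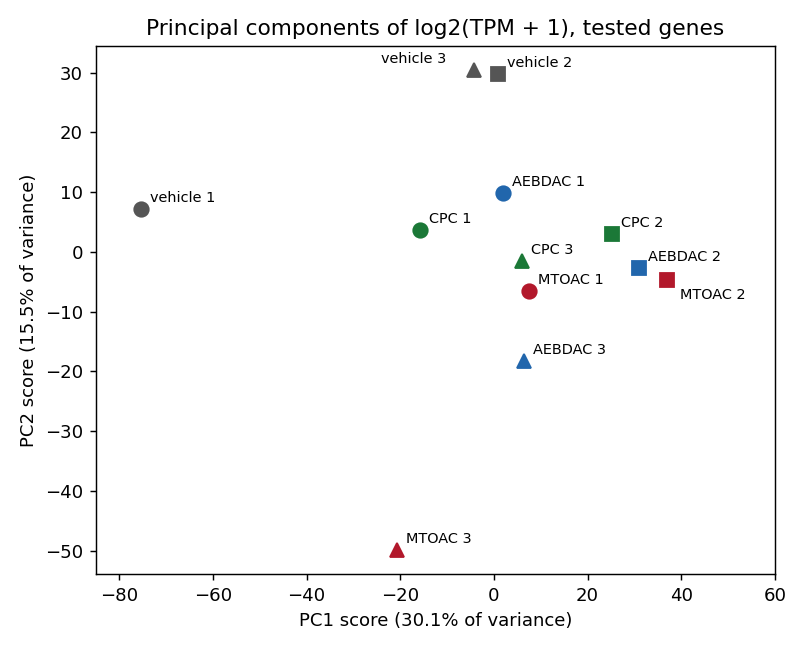
Principal components of log2(TPM + 1) over the 12009 tested genes, with component 1 (30.1% of the variance) on the x axis and component 2 (15.5%) on the y axis, in units of component score; each point is 1 of the 12 libraries, coloured by group. Vehicle library 1 lies at -75.4 on component 1, away from the remaining libraries. MTOAC library 3 lies lowest on component 2, at -49.9.

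CPC raised a few stress-response genes. Chac1, a glutathione-degrading enzyme induced by ATF4, rose from 5.66 ± 2.30 TPM in vehicle to 39.6 ± 6.46 TPM (SD, n = 3), a log2 fold change of 2.66 ± 0.25 (SE). Trib3, a pseudokinase induced in the same response, rose from 3.73 ± 1.31 to 20.4 ± 5.45 TPM (2.18 ± 0.28 log2). Nr4a1, an immediate early nuclear receptor, rose from 15.0 ± 2.45 to 39.3 ± 9.13 TPM (1.32 ± 0.17), and Mthfd2, a mitochondrial enzyme of the folate cycle, from 51.3 ± 4.14 to 118 ± 23.3 TPM (1.17 ± 0.17). Sfpq, a splicing and paraspeckle protein, fell from 228 ± 19.5 to 125 ± 5.55 TPM (-0.86 ± 0.10), and Dll1, a Notch ligand, from 61.0 ± 3.93 to 33.9 ± 4.12 TPM (-0.83 ± 0.12). Adjusted p was 0.00425 for Chac1, 0.0246 for Trib3 and Nr4a1, 0.0331 for Mthfd2 and Dll1 and 0.0115 for Sfpq (limma). Rbmxl1, an RNA-binding protein whose coding sequence is a near copy of Rbmx, so that its reads are uncertain, fell by 0.68 on the log2 scale (adjusted p = 0.0421). The remaining called gene, the unnamed model Gm9775, was named after its values were seen because the count is small. It was listed at 0 in CPC libraries 1 and 3 and at 1.52 TPM in library 2, against 6.84 to 10.1 TPM in vehicle (adjusted p = 0.0331).

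In all, 8 of the 12009 genes passed, 4 higher and 4 lower, with 1634 at an unadjusted p under 0.05 where chance gives 600.45. The groups did not overlap for 20.6% of genes, where chance gives 10%. The median gene lay at -0.17 log2 against vehicle, so that relative to it Chac1 rose by 2.83 and Sfpq fell by 0.69. Without vehicle library 1 the median gene lay at -0.09. With quantile normalization, which removes this shift, 16 genes were called, 12 higher and 4 lower. Sfpq (adjusted p = 0.0539, range over its alternatives 0.00539 to 0.25) and Rbmxl1 (0.111, range 0.0187 to 0.299) were not among them. Replicate numbers paired these libraries, and with the number as a block 184 genes were called, 34 higher and 150 lower, or 115, 79 higher and 36 lower, with quantile normalization and the block. Without 1 library the count was 3, 2 and 5 for vehicle libraries 1, 2 and 3 and 5, 2 and 1 for CPC libraries 1, 2 and 3. Of the 8 genes only Chac1 was called in all 6 of these fits. With only the CPC and vehicle libraries in the fit, limma called 0.

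Targets of ATF4 and CHOP, the transcription factors of the integrated stress response, were higher as a group with CPC. Of 41 members tested, 3 rose (Chac1, Trib3 and Mthfd2), none fell and 38 did not pass, while 8 rose with the replicate block and 9 were higher when adjusted over the list alone; 33 of the 41 had a positive fold change. The median member lay 0.44 log2 above the median gene (camera adjusted p = 2.3e-19; adjusted p = 0.148 with an estimated correlation). Atf4 itself went from 176 ± 43.8 to 336 ± 62.8 TPM (n = 3; 0.94 ± 0.20 log2, adjusted p = 0.12, and 0.0448 with the replicate block). Asns, asparagine synthetase, was listed at 0.142, 1.88 and 0 TPM in vehicle libraries 1 to 3 and at 5.49, 10.2 and 8.14 TPM in CPC libraries 1 to 3; it did not pass (adjusted p = 0.054), and did with the block (0.0304; range over its alternatives 0.0217 to 0.299). Ddit3, which encodes CHOP, differed by less than its spread (8.46 ± 4.09 against 9.04 ± 0.873 TPM, adjusted p = 0.844), and Atf3 was below the filter.

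Immediate early genes, transcribed within minutes of a stimulus, were also higher as a group with CPC. Of 14 tested, 1 rose (Nr4a1), or 2 with the block, 13 did not pass, and 1 was higher when adjusted over the list alone, while 13 had a positive fold change. The median lay 0.68 log2 above the median gene (camera adjusted p = 1.1e-09; adjusted p = 0.344 with an estimated correlation). Without 1 library it ran from 0.43 to 1.03, and the call at the preset correlation stayed. Fos, a subunit of the transcription factor AP-1, stood at 3.30 ± 0.723 and 7.56 ± 2.93 TPM (adjusted p = 0.239). Cell cycle genes were lower as a group: none of 28 passed over all genes, 1 was lower with the block (Ccne1, -0.93 log2, adjusted p = 0.0253 with and 0.124 without it), 12 were lower when adjusted over the list alone, and all 28 had a negative fold change. The median lay at -0.30 relative to the median gene (camera adjusted p = 1.1e-08; adjusted p = 0.344 with an estimated correlation). Mki67, a proliferation marker, stood at 72.3 ± 13.8 and 48.5 ± 2.84 TPM (-0.55 log2, adjusted p = 0.194). With the block the mesenchymal marker list was called as well (adjusted p = 0.0289, against 0.166 without the block), and the number of lists called went from 6 to 7. None of the 6 called lists stayed called with an estimated correlation alone, while 2 did when it was combined with quantile normalization, cell cycle and lysosomal genes (adjusted p = 0.0385 for both).

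**Figure D2:**
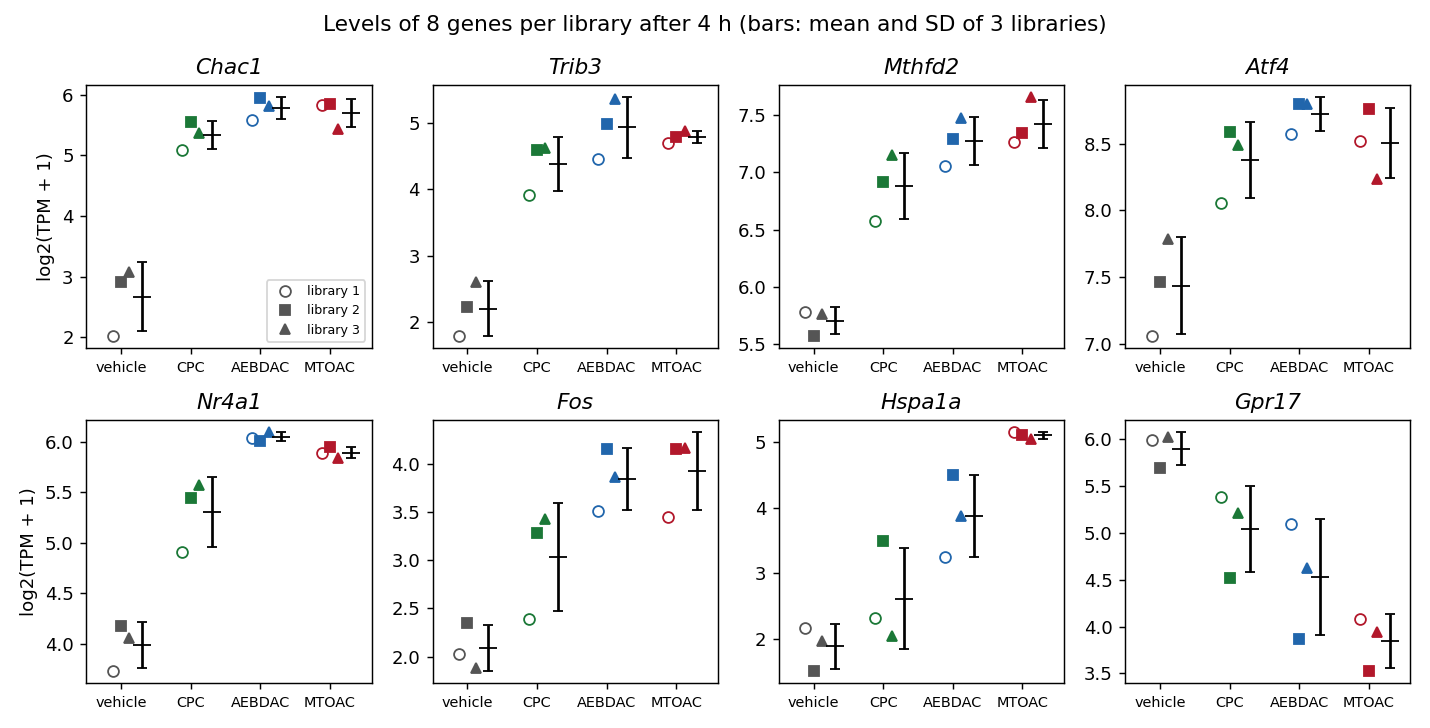
Level of 8 genes as log2(TPM + 1) (y axis) in each of the 4 groups (x axis); each marker is 1 library (circle, library 1; square, 2; triangle, 3) and the bars beside them give the mean and SD of 3 libraries. Chac1, Trib3, Mthfd2 and Nr4a1 lie higher in each compound than in vehicle, Hspa1a lies highest in MTOAC (33.3 TPM against 2.77 in vehicle) and Gpr17 lowest in MTOAC (13.6 against 59.0 TPM).

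AEBDAC raised stress-response genes, among them Chac1 and Trib3, and lowered others. Asns was listed at 10.1, 15.4 and 22.8 TPM in AEBDAC libraries 1 to 3, against 0.142, 1.88 and 0 in vehicle (3.45 ± 0.41 log2, adjusted p = 0.00546). Chac1 rose to 54.2 ± 6.86 TPM (SD, n = 3; 3.11 ± 0.25 log2), Trib3 to 30.7 ± 9.70 TPM (2.73 ± 0.28) and Nr4a1 to 65.4 ± 2.10 TPM (2.06 ± 0.17). Npas4, an activity-regulated transcription factor, rose from 0.810 ± 0.214 to 8.68 ± 1.98 TPM (2.41 ± 0.26). Hspa1a, an inducible HSP70 chaperone, rose from 2.77 ± 0.840 to 14.5 ± 6.52 TPM (1.98 ± 0.38). It has a near-identical copy, Hspa1b, so the division of reads between them is uncertain. The lowest fold changes were those of Rbm12, an RNA-binding protein gene that overlaps Cpne1 on the same strand (13 ± 1.05 to 2.23 ± 1.44 TPM, -2.23 ± 0.31), Armc10 (-1.74 ± 0.29), Vmac (-1.65 ± 0.29), Rfx5 (-1.60 ± 0.33), Snn (-1.52 ± 0.28) and Tpra1 (-1.41 ± 0.26). Vmac and Snn overlap protein-coding genes on the other strand, so their reads are uncertain too. Adjusted p was 0.000531 for Chac1 and Nr4a1 and between 0.00279 and 0.0479 for the others.

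With AEBDAC 153 genes passed, 47 higher and 106 lower, with 2301 at an unadjusted p under 0.05 and non-overlapping groups for 24.9% of genes, where chance gives 10%. The median gene lay at -0.16 log2, and at -0.07 without vehicle library 1. With quantile normalization the split was 96 higher and 86 lower of 182, 116 of the 153 being among them. Without 1 library the count was 36, 12 and 38 for vehicle libraries 1, 2 and 3 and 104, 9 and 10 for AEBDAC libraries 1, 2 and 3. Of the 27 called genes named in the text for AEBDAC, 8 were called in all 6 of these fits (Asns, Chac1, Trib3, Npas4, Nr4a1, Mthfd2, Sfpq and Dll1) and 27 kept their sign. With only the AEBDAC and vehicle libraries in the fit, 3 genes were called. The rule for pairing was not met here, and with the replicate number as a block 1072 genes were called, 225 higher and 847 lower. Quantile normalization with the block gave 907, 487 higher and 420 lower.

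Of the 41 integrated stress response targets 8 rose with AEBDAC, none fell and 33 did not pass, and 17 were higher when adjusted over the list alone. Besides Chac1, Trib3 and Asns, these included Mthfd2 (155 ± 22.3 TPM, n = 3, 1.57 ± 0.17 log2, adjusted p = 0.00337) and Atf4 (423 ± 36.5 TPM, 1.29 ± 0.20, adjusted p = 0.0207). The median lay 0.67 log2 above the median gene (camera adjusted p = 8.1e-21; adjusted p = 0.121 with an estimated correlation). Of 14 immediate early genes 2 rose, Nr4a1 and Fos (13.6 ± 3.19 TPM, 1.75 ± 0.30 log2, adjusted p = 0.032), and 7 were higher when adjusted over the list alone. The median lay 0.999 log2 above the median gene (camera adjusted p = 9.1e-12; adjusted p = 0.264 with an estimated correlation). Of 28 cell cycle genes 4 fell and 24 did not pass, and 11 were lower when adjusted over the list alone (median -0.35 relative to the median gene, camera adjusted p = 7.0e-07; adjusted p = 0.428 with an estimated correlation). These included Aurka and Aurkb, mitotic kinases, at -0.84 ± 0.15 and -0.61 ± 0.12 log2, and Ccne1, cyclin E1 of the entry into S phase, at -1.16 ± 0.21; Aurkb lost its call with quantile normalization. Mki67 did not pass (-0.66 log2, adjusted p = 0.0651), and did with quantile normalization (0.0474; range over its alternatives 0.0223 to 0.223).

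Among single genes of other lists, Olig1 fell with AEBDAC from 1194 ± 154 to 682 ± 127 TPM (n = 3; -0.82 ± 0.16 log2, adjusted p = 0.0404), the 1 called gene of 20 OPC markers (2 lower when adjusted over the list alone; camera adjusted p = 0.669). Herpud1, a component of endoplasmic reticulum degradation, rose from 19.7 ± 3.71 to 47.3 ± 7.85 TPM (1.22 ± 0.17, adjusted p = 0.0151), and Hmox1, heme oxygenase 1, from 46.8 ± 8.62 to 87.2 ± 13.5 TPM (0.89 ± 0.18, adjusted p = 0.0406). Arl4c, a small GTPase gene induced by LXR, rose by 0.97 ± 0.20 (adjusted p = 0.0484). Elovl6, a fatty acid elongase, and Dnaja1, an HSP40 co-chaperone, fell by 0.65 and 0.51 on the log2 scale (adjusted p = 0.0464 and 0.038). Olig1 and Hmox1 kept the call without AEBDAC library 1 and lost it without each of the other 5 libraries, and Arl4c, Elovl6 and Dnaja1 lost it without any 1 of the 6.

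MTOAC gave the most calls. Hspa1a rose from 2.77 ± 0.840 to 33.3 ± 1.27 TPM (SD, n = 3; 3.21 ± 0.38 log2) and Hspa1b from 5.09 ± 1.5 to 37.0 ± 1.87 TPM (2.67 ± 0.35), the 2 being near-identical copies whose reads are uncertain. Asns was listed at 12.2, 9.75 and 16.0 TPM in MTOAC libraries 1 to 3 (3.18 ± 0.41), Chac1 rose to 51.4 ± 8.02 TPM (3.03 ± 0.25), Trib3 to 26.7 ± 1.74 TPM (2.58 ± 0.28) and Npas4 to 8.69 ± 2.17 TPM (2.40 ± 0.26). The lowest fold changes were those of Ubap2, a ubiquitin-associated protein gene (31.1 ± 12.9 to 2.22 ± 1.77 TPM, -3.37 ± 0.63), Nrarp, a Notch-regulated ankyrin repeat gene (-2.49 ± 0.48), Rbm12 (-2.20 ± 0.31) and Lims2 (-2.13 ± 0.56). Btg2, an antiproliferative p53 target, fell from 133 ± 17.5 to 32.1 ± 13.4 TPM (-2.08 ± 0.38). Gpr17, a receptor of committed OPCs, fell from 59.0 ± 7.19 to 13.6 ± 2.79 TPM (-2.05 ± 0.30). Lims2 and Gpr17 overlap on opposite strands, so without strand their reads are uncertain. Adjusted p lay between 0.0006 for Chac1 and 0.0472 for Lims2. Lims2 lost its call with quantile normalization and without vehicle libraries 1 and 3 and MTOAC libraries 1, 2 and 3 (highest adjusted p = 0.204). Nrarp lost it without vehicle libraries 1 and 3 and MTOAC library 2 (highest 0.0654), and Ubap2 and Btg2 without MTOAC library 2 (highest 0.0634 and 0.0621).

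With MTOAC 785 genes passed, 95 higher and 690 lower, so that 87.9% were lower, with 2926 at an unadjusted p under 0.05 and non-overlapping groups for 26.4% of genes, where chance gives 10%. The median gene lay at -0.22 log2, and at -0.14 without vehicle library 1. With quantile normalization 430 genes were called, 213 higher and 217 lower, of which 306 were among the 785 and none had turned in sign. Of the 46 called genes named in the text for MTOAC, 23 were called without any 1 of the 6 libraries and 46 kept their sign. Without 1 library the count was 305 (57 higher and 248 lower), 323 and 331 for vehicle libraries 1, 2 and 3 and 275, 149 and 573 for MTOAC libraries 1, 2 and 3. With only the MTOAC and vehicle libraries in the fit, 17 genes were called. The rule for pairing was not met here either, and with the replicate number as a block 1904 genes were called, 245 higher and 1659 lower. Quantile normalization with the block gave 1194, 620 higher and 574 lower.

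OPC markers included 3 called genes with MTOAC, each lower. Gpr17 fell by 2.05 on the log2 scale, Olig1 from 1194 ± 154 to 531 ± 79.0 TPM (n = 3; -1.17 ± 0.16, adjusted p = 0.00647) and Pdgfra from 31.4 ± 3.62 to 13.3 ± 3.06 TPM (-1.20 ± 0.28, adjusted p = 0.0319). Of the 20 markers tested 17 did not pass, and 3 were lower when adjusted over the list alone; the list was not called against other genes (median -0.17 relative to the median gene, camera adjusted p = 0.217). Olig2 stood at 459 ± 96.3 and 333 ± 62.0 TPM (-0.46 log2, adjusted p = 0.156) and Sox10, a lineage transcription factor, at 41.9 ± 20.9 and 18.3 ± 9.82 TPM (adjusted p = 0.335). The Pdgfra call was lost with quantile normalization (adjusted p = 0.123; range over its alternatives 0.0146 to 0.135) and without any 1 of the 6 libraries. Among myelin and differentiation genes 1 of 11 fell, Cnp, a myelin enzyme, at -0.63 ± 0.13 log2 (adjusted p = 0.0232), lost with quantile normalization and without vehicle libraries 1 and 3 and MTOAC library 2; 1 was lower when adjusted over the list alone, and the list was not called (adjusted p = 0.641). Mbp (2.19 ± 1.99 TPM) differed from vehicle by less than its spread, and Myrf was below the filter, at under 1 TPM in each library.

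Of the 41 integrated stress response targets 10 rose with MTOAC, none fell and 31 did not pass, and 16 were higher when adjusted over the list alone. Mthfd2 rose to 172 ± 25.8 TPM (n = 3; 1.72 ± 0.17 log2, adjusted p = 0.00109) and Atf4 to 366 ± 65.4 TPM (1.07 ± 0.20, adjusted p = 0.0162), the latter not called without MTOAC library 2. The median lay 0.78 log2 above the median gene (camera adjusted p = 6.0e-22; adjusted p = 0.105 with an estimated correlation). Ddit3 stood at 15.1 ± 5.80 TPM (0.80 ± 0.31 log2, adjusted p = 0.145). Of 14 immediate early genes 2 rose, Nr4a1 (58.5 ± 2.29 TPM, 1.91 ± 0.17) and Fos (14.6 ± 3.99 TPM, 1.83 ± 0.30, adjusted p = 0.0119), and 7 were higher when adjusted over the list alone (median 1.03 above the median gene, camera adjusted p = 1.7e-12; adjusted p = 0.231 with an estimated correlation). Of 28 cell cycle genes 9 fell and 19 did not pass, and 17 were lower when adjusted over the list alone (median -0.43 relative to the median gene, camera adjusted p = 2.7e-06; adjusted p = 0.35 with an estimated correlation). They included Mki67 (39.0 ± 6.53 TPM, -0.87 ± 0.15), Plk1, a mitotic kinase (-0.96 ± 0.14), Aurkb (-0.74 ± 0.12) and Ccne1 (-1.23 ± 0.21). Adjusted p for these ranged from 0.00677 to 0.0141, and Mki67 lost its call without MTOAC library 2.

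Heat shock genes went both ways with MTOAC. Of 18 tested, Hspa1a and Hspa1b rose, 2 fell, among them Dnaja1 (-0.62 ± 0.09 log2, adjusted p = 0.00823), and 14 did not pass, while 2 were higher and 3 lower when adjusted over the list alone. The median of the list lay at -0.02 relative to the median gene, and the test, whose direction was up, did not call it (camera adjusted p = 0.515). Of 23 endoplasmic reticulum chaperone genes driven by ATF6 and XBP1, Herpud1 rose (47.5 ± 5.73 TPM, n = 3, 1.23 ± 0.17 log2, adjusted p = 0.00677) and Syvn1, an endoplasmic reticulum ubiquitin ligase, fell by 0.73 (adjusted p = 0.0165), a call lost without MTOAC libraries 1 and 2 (highest adjusted p over its alternatives 0.124). Hspa5, the main chaperone of this compartment, stood at 312 ± 91.5 and 275 ± 50.4 TPM (adjusted p = 0.695), and the list was not called (adjusted p = 0.519; 1 higher and 1 lower when adjusted over the list alone). Hmox1 rose to 83.4 ± 10.2 TPM (0.83 ± 0.18, adjusted p = 0.0242), the 1 called gene of 19 NRF2 targets (1 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.365); it was not called without vehicle libraries 1 and 2 and MTOAC library 2.

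Lipid genes changed singly with MTOAC. Of 24 genes of cholesterol synthesis 3 fell, among them Mvk and Fdps (-0.78 ± 0.15 and -1.11 ± 0.22 log2; adjusted p = 0.0181 and 0.0184), and 5 were lower when adjusted over the list alone. Hmgcs1, an early enzyme of the pathway, stood at 851 ± 161 and 691 ± 142 TPM (n = 3; adjusted p = 0.291). Of 15 genes of fatty acid synthesis 2 fell, Fasn, fatty acid synthase (-0.67 ± 0.17, adjusted p = 0.0419), and Elovl6 (-0.79 ± 0.13, adjusted p = 0.0128), and 2 were lower when adjusted over the list alone. Neither list was called (adjusted p = 0.937 and 0.173), and the calls of Mvk, Fdps and Fasn were lost with quantile normalization. They were also lost without 1 library, for Mvk vehicle libraries 2 and 3 and MTOAC library 2, for Fdps vehicle library 3 and MTOAC library 2, and for Fasn each but MTOAC library 3 (highest adjusted p over the alternatives 0.124, 0.0968 and 0.141). The cholesterol list had a median 0.09 above the median gene. Arl4c rose by 0.94 ± 0.20, the 1 called gene of 10 LXR targets (adjusted p = 0.0269), a call lost without vehicle libraries 1 and 2 and MTOAC libraries 1 and 3 (highest adjusted p over its alternatives 0.0974); 1 was higher and 1 lower when adjusted over the list alone, and the list was not called (adjusted p = 0.259).

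The remaining lists held few called genes with MTOAC. Bcl2l11 and Diablo, which promote apoptosis, fell by 1.10 and 0.54 on the log2 scale, 2 of 16 apoptosis genes, and Nfkbie, an inhibitor of NF-kB, fell by 1.06, 1 of 7 inflammatory genes; all 3 calls (adjusted p = 0.04, 0.047 and 0.0386) were lost with quantile normalization and without any 1 of the 6 libraries. Btg2 was the 1 called gene of 19 p53 targets, and Cdkn1a and Bbc3, which p53 induces, differed by 0.16 and -0.33 log2 (adjusted p = 0.762 and 0.73). Map2, a neuronal microtubule gene, fell by 0.67 (adjusted p = 0.0155), 1 of 12 neuronal markers, a call lost without MTOAC libraries 1 and 2 (highest adjusted p over its alternatives 0.116). When adjusted over the list alone, 2 apoptosis, 1 inflammatory, 1 p53 and 2 neuronal genes were lower. Camera did not call these lists (adjusted p = 0.676 for apoptosis, 0.259 for inflammatory, 0.215 for p53 and 0.676 for neuronal genes), nor 10 astrocyte markers (0.217), 26 nuclear oxidative phosphorylation genes (0.494) or 19 genes of glycolysis and hypoxia (0.456), of which no member was called.

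These lists were not called with CPC or AEBDAC either. For CPC adjusted p was 0.985 for endoplasmic reticulum chaperones, 0.73 for cholesterol synthesis, 0.122 for fatty acid synthesis, 0.136 for LXR targets, 0.96 for both OPC markers and myelin genes, 0.934 for NRF2 targets, 0.73 for heat shock genes and 0.757 for apoptosis genes. Values were 0.315 for astrocyte and 0.73 for neuronal markers, 0.173 for p53 targets, 0.417 for inflammatory genes, 0.271 for nuclear oxidative phosphorylation and 0.874 for glycolysis. No member of these lists was called with CPC by limma without the block. With the block, 1 LXR target, Arl4c (0.72 log2), and 1 NRF2 target, Hmox1 (0.62), were higher. Lower with it were 1 LXR target, the OPC marker Gpr17 (-0.86), the myelin gene Cnp (-0.55), 2 p53 targets, among them Btg2 (-1.13), and the heat shock gene Dnaja1 (-0.47). Adjusted p with the block was 0.0304 for Arl4c, Cnp and Btg2, 0.0352 for Hmox1, 0.0450 for Gpr17 and 0.0454 for Dnaja1, and over their alternatives it ranged up to 0.633. When adjusted over the list alone, 1 endoplasmic reticulum chaperone and 1 LXR target were higher and 1 gene each of fatty acid synthesis, LXR targets, myelin and heat shock lower. For AEBDAC the adjusted p of the lists not called lay between 0.103, for mesenchymal markers, and 0.982, for cholesterol synthesis and myelin genes. When adjusted over the list alone, the members that passed with AEBDAC were 1 endoplasmic reticulum chaperone, 1 LXR target, 1 NRF2 target, 2 heat shock genes and 1 inflammatory gene higher, and 3 cholesterol, 1 fatty acid, 2 OPC marker, 1 myelin, 1 neuronal, 1 p53, 2 heat shock and 1 inflammatory gene lower.

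Ribosomal and lysosomal genes were higher than the median gene with each compound, though no member of either list passed over all genes and, adjusted over the list alone, only 1 lysosomal gene with CPC. For 36 ribosomal protein genes the median lay 0.24, 0.27 and 0.33 log2 above the median gene with CPC, AEBDAC and MTOAC (camera adjusted p = 3.2e-06, 0.000122 and 4.3e-06; adjusted p = 0.344, 0.508 and 0.35 with an estimated correlation), and with quantile normalization the list was not called. For 22 genes of lysosomes and autophagy it lay 0.18, 0.26 and 0.31 above (adjusted p = 0.00557, 0.00417 and 0.00315; adjusted p = 0.344, 0.428 and 0.35 with an estimated correlation), and the CPC call was lost without vehicle library 2 (0.14, adjusted p = 0.0976). The 13 mitochondrially encoded genes lay 0.31 above with CPC and 0.34 with MTOAC (adjusted p = 0.00246 and 0.0198; adjusted p = 0.437 and 0.492 with an estimated correlation) and 0.18 with AEBDAC, not called. Their direction turned with quantile normalization, to -0.13 and -0.07 for CPC and MTOAC, and without vehicle library 1, the library with the lowest sum over these genes, to -0.08 and -0.10. The calls were also lost without CPC library 1 (0.20, adjusted p = 0.13) and MTOAC library 1 (0.30, adjusted p = 0.208), and for MTOAC with no filter on low values (0.19, adjusted p = 0.08). Of 5 mesenchymal markers tested none was called, and the list lay 0.48 above with MTOAC (adjusted p = 0.039; adjusted p = 0.25 with an estimated correlation). That call was lost with quantile normalization, with no filter on low values (0.17, adjusted p = 0.0566; range over its alternatives 0.0016 to 0.258) and without vehicle library 1 and MTOAC library 1.

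**Figure D3:**
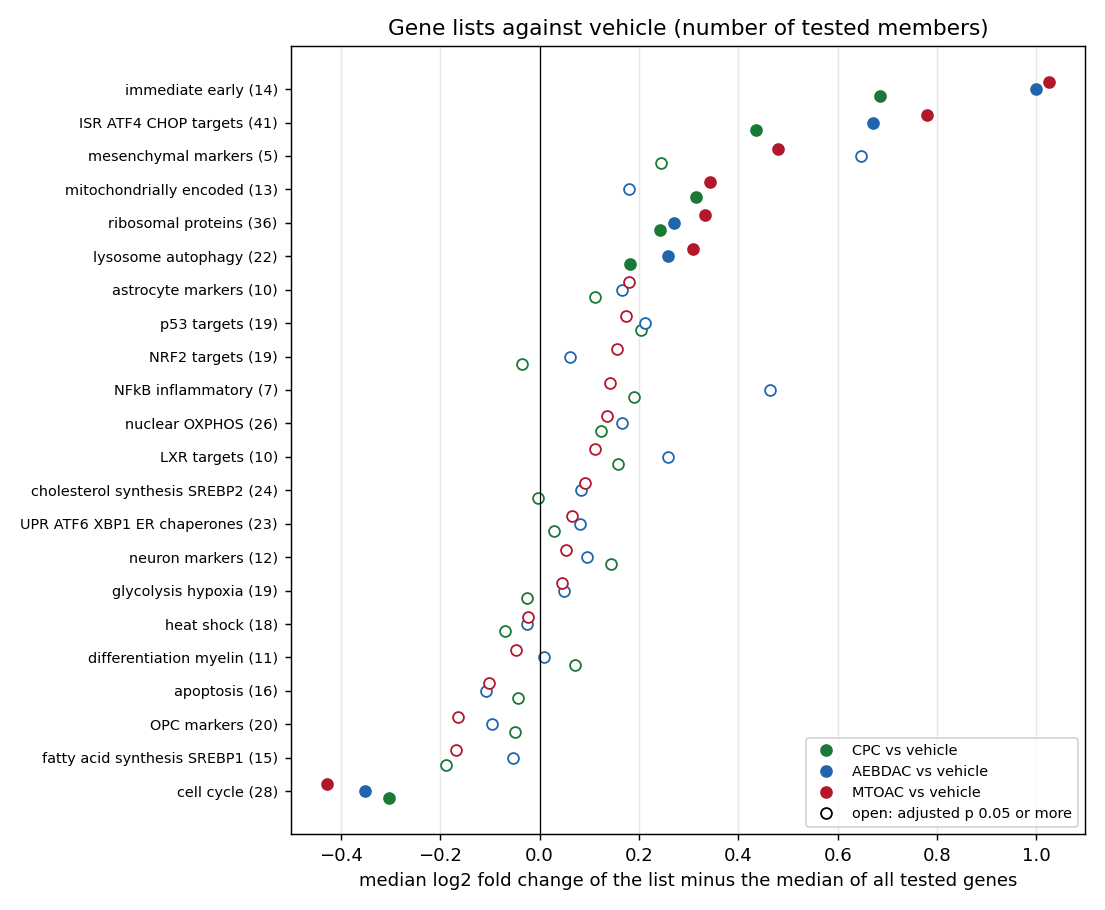
Median log2 fold change of the tested members of each of 22 gene lists minus the median of all tested genes (x axis, log2) for each list (y axis) and compound against vehicle (colour); filled symbols have an adjusted p under 0.05 by camera with a preset correlation, and none does with an estimated correlation. Integrated stress response targets (0.44, 0.67 and 0.78) and immediate early genes (0.68, 0.999 and 1.03) lie to the right for CPC, AEBDAC and MTOAC, and cell cycle genes (-0.30, -0.35 and -0.43) to the left.

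The 3 compounds shared 7 called genes, each in 1 direction: Chac1, Trib3, Nr4a1 and Mthfd2 rose, and Sfpq, Dll1 and Rbmxl1 fell. In the GRCm38 annotation (mm10) Chac1 lies on chromosome 2 from 119351229 to 119354381 and Trib3 on the same chromosome from 152337422 to 152344032. Mthfd2 lies on chromosome 6 from 83305691 to 83325908, Nr4a1 on 15 from 101254269 to 101274795, Sfpq on 4 from 127021324 to 127037013, Dll1 on 17 from 15367354 to 15376872 and Rbmxl1 on 8 from 78505269 to 78508898. All 7 are annotated as protein-coding, and the values are sums over whole genes. Sfpq lay at -0.81 ± 0.10 and -1.11 ± 0.10 log2 and Dll1 at -0.98 ± 0.12 and -1.36 ± 0.12 log2 with AEBDAC and MTOAC. With the replicate number as a block 169 genes were shared, 32 higher and 137 lower, though AEBDAC and MTOAC against vehicle did not meet the rule for pairing. The overlap was 14 genes under quantile normalization, and 113, 79 higher and 34 lower, with the block besides. Without 1 library it was 3, 2 and 3 for vehicle libraries 1, 2 and 3, 1 for CPC libraries 2 and 3, 2 and 4 for AEBDAC libraries 2 and 3, and 2, 4 and 16 for MTOAC libraries 1, 2 and 3.

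AEBDAC and MTOAC shared 143 called genes, 41 higher and 102 lower, where independent lists would share 0.372 and 6.09. CPC shared 7 with AEBDAC and 8 with MTOAC. Because the comparisons use the same 3 vehicle libraries, unchanged groups were simulated against them: 100 such data sets shared a mean of 0, 6.72 and 0 called genes for CPC with AEBDAC, CPC with MTOAC and AEBDAC with MTOAC, and at most 0, 672 and 0. Across genes, which are not independent replicates, the fold changes of these pairs correlated at 0.755, 0.725 and 0.766, against means of 0.434, 0.457 and 0.484 in the simulations. Their covariances were 0.142, 0.141 and 0.172, against simulated means of 0.0687, 0.0747 and 0.0778, so that 0.0730, 0.0664 and 0.0944 remained. All lay within the simulated ranges, whose upper bounds were 0.869, 0.913 and 0.903 for the correlations and 0.206, 0.238 and 0.248 for the covariances, so unchanged groups reach such values. The simulated libraries did not keep the replicate numbers, so these ranges may not hold for libraries paired by number. The 3 controls are too few to split into parts of 2, and part of the excess may come from the shared controls.

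Between compounds no gene passed, while some lists did, and the doses differed. Relative to CPC, Nr4a1 was higher by 0.75 log2 with AEBDAC (95% interval 0.37 to 1.12) and by 0.59 with MTOAC (0.21 to 0.96), and Mthfd2 by 0.40 (0.03 to 0.76) and 0.54 (0.18 to 0.91); all 4 had an adjusted p of 1 (limma). Hspa1a stood at 5.78 ± 3.86 TPM with CPC, the pyridinium compound, at 14.5 ± 6.52 with AEBDAC, the ethylbenzyl compound, and at 33.3 ± 1.27 with MTOAC, the compound with no aromatic ring (SD, n = 3). Each structure came as 1 compound at its own dose, so these levels cannot be tied to structure. The MTOAC to CPC difference was 2.48 log2 (95% interval 1.65 to 3.31, adjusted p = 0.379) and that of its near copy Hspa1b 2.15 (1.39 to 2.92, adjusted p = 0.379); both were named here after their values were seen. Without CPC library 2 Hspa1a was called (2.92 log2, adjusted p = 0.0423; range over its alternatives 0.0423 to 1), and both were higher when adjusted over the heat shock list alone. With MTOAC, Gpr17 lay at -1.19 (-1.86 to -0.52) and Olig1 at -0.56 (-0.91 to -0.21) relative to CPC, with an adjusted p of 1. Chac1 differed by 0.45 (-0.11 to 1.0) between AEBDAC and CPC, 0.37 (-0.19 to 0.92) between MTOAC and CPC and -0.08 (-0.63 to 0.48) between MTOAC and AEBDAC. Trib3 differed by 0.56 (-0.05 to 1.17), 0.41 (-0.20 to 1.02) and -0.15 (-0.76 to 0.46), so differences of up to 1.0 log2 in Chac1 and 1.17 in Trib3 are not excluded. Pdgfra differed by -0.61 (-1.22 to -0.01) between MTOAC and AEBDAC, again with an adjusted p of 1.

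Among lists, integrated stress response targets were higher with AEBDAC than with CPC by a median of 0.27 log2 relative to the median gene (33 of 41 positive; camera adjusted p = 1.4e-06; adjusted p = 0.953 with an estimated correlation) and with MTOAC than with CPC by 0.30 (32 of 41; adjusted p = 1.1e-07; adjusted p = 0.582 with an estimated correlation). Without 1 library these medians ran from 0.14 to 0.38 and from 0.19 to 0.33. Immediate early genes were higher by 0.35 (14 of 14; adjusted p = 3.8e-05; adjusted p = 0.953 with an estimated correlation) and 0.48 (12 of 14; adjusted p = 1.4e-05; adjusted p = 0.59 with an estimated correlation). OPC markers were lower with MTOAC than with CPC by -0.26 (16 of 20 negative; adjusted p = 0.0045; adjusted p = 0.126 with an estimated correlation). No member of these lists passed over all genes; adjusted over the list alone, 1 immediate early gene passed for AEBDAC against CPC and 2 OPC markers for MTOAC against CPC. The immediate early calls were lost without CPC library 1, and also without AEBDAC library 3 in the first comparison and MTOAC library 2 in the second; the OPC marker call was lost without CPC library 3. Between MTOAC and AEBDAC camera called 0 of 22 lists, and 1, the OPC markers, with the replicate block (adjusted p = 0.0421), where the numbers paired the libraries. The OPC markers were not called there with an estimated correlation (adjusted p = 0.548) or with quantile normalization (0.128).

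By limma 0 genes passed for AEBDAC against CPC, MTOAC against CPC and MTOAC against AEBDAC, with 211, 449 and 307 at an unadjusted p under 0.05, where chance gives 600.45, and lowest adjusted p of 1, 0.379 and 1. Groups did not overlap for 6.88%, 8.60% and 6.94% of genes, where chance gives 10%. Both chance values assume that the libraries are exchangeable. Same-numbered libraries of AEBDAC and CPC and of MTOAC and AEBDAC deviated together, which can put such values below chance. This may not be the whole source, since MTOAC against CPC, which did not meet the rule for pairing, was low too. With the replicate number as a block, the counts for AEBDAC against CPC and MTOAC against AEBDAC stayed under 600.45, at 415 and 527. Fits of only the 2 groups, which leave out vehicle library 1, gave 339, 426 and 301 at an unadjusted p under 0.05. The cause was not tested. The low values therefore do not show that the compounds acted alike. Limma without trend and robust fitting also called 0, as did the replicate block, with 415, 825 and 527 at an unadjusted p under 0.05. With only the 2 groups in the fit the counts were 1, 0 and 1, and without CPC library 2 MTOAC against CPC gave 1. In simulated data of this design 51%, 53% and 58% of genes changed by 1 log2 were called in these comparisons, and 95%, 88% and 90% of those changed by 2 log2. The simulated data had independent noise and no effect of the replicate number, so these rates may not hold for the real libraries.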

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

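The comparisons in this part, including the other splits of the libraries, were planned before the data were examined. None of its tests was chosen after the result was seen. The written predictions did not name the counts over splits that part all 3 pairs of same-numbered libraries, however. In 5 cases the effects of 2 compounds on a gene list, each set against the shared vehicle, differed by a test of the difference itself, camera with the preset correlation, and in none of them with an estimated correlation. Integrated stress response targets lay 0.268 log2 further above the median gene with AEBDAC than with CPC (33 of 41 genes positive; camera adjusted p = 1.37e-06, 0.953 with an estimated correlation) and 0.297 with MTOAC than with CPC (32 of 41; 1.11e-07, 0.582 with an estimated correlation). Without any 1 library both calls at the preset correlation stayed, with differences of 0.140 to 0.377 and 0.188 to 0.330. For immediate early genes such as Nr4a1 and Fos these differences were 0.352 (14 of 14 positive; 3.77e-05, 0.953 with an estimated correlation), not called without CPC library 1 (0.07, adjusted p = 0.374) or AEBDAC library 3 (0.16, 0.0705), and 0.478 (12 of 14; 1.4e-05, 0.59 with an estimated correlation), not called without CPC library 1 (0.20, 0.0968) or MTOAC library 2 (0.31, 0.0666). OPC markers, led by Gpr17 and Olig1, lay at -0.256 with MTOAC relative to CPC (16 of 20 negative; 0.0045, 0.126 with an estimated correlation), and the call was lost without CPC library 3 (-0.17, 0.0756). The doses of the compounds differed.

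The 3 libraries against 3 allow 10 splits, too few for a share under 0.05. For AEBDAC against CPC, where numbers paired the libraries, the real split called 2 lists; 7 of the 10 splits called as many, the highest other 7, but the other splits that parted all 3 pairs called at most 0. For MTOAC against CPC the real split called 3 lists, 7 of the 10 called as many, and the highest other called 8. Of its other splits that parted all 3 pairs the highest called 3, as many as the real one. For MTOAC against AEBDAC, also paired, the real split called 0 lists, so that all 10 splits called as many; the highest other called 8 and the highest of those that parted all 3 pairs 2. The splits that part fewer pairs set libraries of the same number together, so they carry the differences between numbers. Of single genes the real splits of these comparisons called 0, all 10 splits called as many, and the highest other splits called 1, 1 and 3.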

How the results depend on the processing

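Each alternative changed 1 choice and kept the rest; quantile normalization combined with the block, with leaving out vehicle library 1 or with an estimated correlation was chosen after the data were seen. Of 2388 gene values, 1958 kept direction and side of the threshold, 406 lost the call and 24 gained it, none reversed; of 340 list values 266 kept both, 64 lost the call and 10 reversed; of 195 counts 116 stayed within 1.5 times and 79 moved. Genes called numbered 8 for CPC, 153 for AEBDAC and 785 for MTOAC against vehicle, and 7 in all 3. The corresponding counts were 16 (CPC), 430 (MTOAC) and 14 (all 3) with quantile normalization; 38 (AEBDAC) and 404 (MTOAC) with no filter; 1 (CPC), 75 (AEBDAC) and 1 (all 3) without trend and robust fitting; 0, 3, 17 and 0 with only the 2 groups compared, where fewer samples set the variance; 5, 65, 274 and 4 with the fold minimum, a stricter rule by construction; and 4, 41, 224 and 4 with quantile normalization without vehicle library 1. Without 1 library they ran from 1 to 5, 9 to 104, 149 to 573 and 1 to 16. Between compounds no filter gave 1 gene for AEBDAC and for MTOAC against CPC, the fit of only 2 groups 1 for AEBDAC against CPC and for MTOAC against AEBDAC, and leaving out 1 library 0 to 1 for MTOAC against CPC. Lists called numbered 6, 5 and 7 against vehicle and 2, 3 and 0 between compounds. An estimated correlation gave 0 in all 6 comparisons, quantile normalization 4 for MTOAC, and quantile normalization with an estimated correlation 2 for CPC and 0 in the other 5. Without 1 library they ran from 5 to 8, 5 to 7, 5 to 9, 1 to 4, 2 to 6 and 0 to 4. Except where the construction is named, the cause was not tested. The fit of only 2 groups also drops the spread of the others, so fewer samples alone may not explain its lower counts against vehicle. Mean correlations of libraries with their own group were 0.919 to 0.942 for vehicle and 0.939 to 0.953 for MTOAC. They were 0.955 to 0.962 for CPC and 0.958 to 0.960 for AEBDAC. A spread shared over all 4 groups may therefore be too small for MTOAC against vehicle, which was not tested.

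The mitochondrially encoded list reversed, at a median of -0.134 for CPC and -0.0693 for MTOAC against 0.31 and 0.34, with quantile normalization, alone, with the block or with an estimated correlation; at -0.132 and -0.228 with quantile normalization without vehicle library 1; and at -0.0756 and -0.104 without vehicle library 1, the lowest of ranges that reached 0.626 and 0.584. With the replicate number as a block the genes called were 184 for CPC, 1072 for AEBDAC, 1904 for MTOAC and 169 in all 3, and with quantile normalization besides 115, 907, 1194 and 113. For AEBDAC and MTOAC against vehicle and MTOAC against CPC the rule for pairing was not met. Correlations of same-numbered libraries were 0.08, 0.25 and 0.03, then -0.03, 0.35 and -0.19, and then 0.17, 0.40 and 0.09. Yet the own number correlated best in 29 of 36 checks over all groups. The Y chromosome genes Eif2s3y and Ddx3y were also listed at 0 in the library numbered 2 of all 4 groups. This sets number 2 apart in every comparison and does not part number 1 from 3. The 3 comparisons that met the rule, however, link same-numbered libraries across all 4 groups. These are hints from the data, as the labels state no pairing. Fits without the block may therefore ignore a pairing in AEBDAC and MTOAC against vehicle and MTOAC against CPC too. The block called 5 lists for MTOAC against CPC and 1 for MTOAC against AEBDAC. Hmox1 with CPC (0.62) had an adjusted p of 0.198 without and 0.0352 with the block. In the paired comparisons it changed no other call of a list or named gene beyond those given with the results. Read counts were not used here, so how depth limits calls at low TPM could not be measured.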

Other observations

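The tests on Notch and SR splicing factor lists, on the culture or strain of the libraries numbered 1, on the scaling of the values, on assignments within replicate numbers and on vehicle library 1 as the source of the falls with MTOAC were chosen after the results were seen; the others were not. Some genes of RNA splicing were lower with MTOAC. Of 22 SR splicing factors and their partners, 14 did not pass and 8 fell, among them Srsf3, which also regulates mRNA export (233 ± 7.05 to 98.6 ± 7.35 TPM, SD, n = 3; -1.23 ± 0.17 log2, adjusted p = 0.00647), Srsf7 (-0.53 ± 0.10, adjusted p = 0.0151), Srsf6 (-0.73 ± 0.14, adjusted p = 0.0153) and Sfpq. The list lay at -0.24 relative to the median gene (camera adjusted p = 0.000192, 3.2e-05 unadjusted; adjusted p = 0.0761 with an estimated correlation). It was drawn up after some of its members had been seen to fall, so this test is void and a fall of the group stays open. Srsf1, Srsf6 and Srsf7 each lost the call in at least 1 fit without 1 library, MTOAC library 2 among those for all 3, and Srsf1 and Srsf7 lost it with quantile normalization.

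Several genes of the Notch pathway were called with MTOAC, and not in 1 direction. Dll1, a ligand, fell by 1.36 on the log2 scale (adjusted p = 0.0006), Hes5, a repressor induced by Notch, from 148 ± 31.7 to 38.0 ± 8.77 TPM (SD, n = 3; -1.94 ± 0.36, adjusted p = 0.0151), Nrarp by 2.49 and Lfng, a modifier of Notch receptors, by 0.68 (adjusted p = 0.0462). Jag1, another ligand, rose from 13.2 ± 1.61 to 26.8 ± 6.90 TPM (0.95 ± 0.18, adjusted p = 0.0173). Of 21 pathway genes tested no others were called. The list did not stand apart from other genes (camera adjusted p = 0.223, 0.149 unadjusted), but it too was drawn up from genes seen to fall, so the test decides nothing about the group. The Lfng call was lost with quantile normalization and without any 1 of the 6 libraries, that of Jag1 without vehicle library 1 and that of Nrarp without vehicle libraries 1 and 3 and MTOAC library 2.

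The counts of splits and assignments below include the real one. Vehicle library 1 stood apart from all other libraries, the other vehicle libraries included. A culture or strain shared by the libraries numbered 1 would put mt-Nd3 near 0 in those too, but its lowest level in them was 9628 TPM. Assignment of mitochondrial reads as the whole cause is argued against by the 11217 genes left without mitochondrial genes and unnamed models, where the correlation of vehicle libraries 2 and 3 across genes exceeded those with library 1 by a mean of 0.0385 (0.964 against 0.928 and 0.923). A bias by transcript length or GC content may contribute: these explained 5.91% of the variance over genes between library 1 and the other 2, between the bounds set for and against it, and 6.64% for MTOAC library 3. No biological explanation was tested, since the labels give none for a single vehicle library.

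More genes fell than rose with MTOAC. Vehicle library 1 as the whole source is argued against by the fit without it, in which 81.3% of called genes fell against 87.9% with it. After a correction for length and GC content 86.8% fell (99.6% of genes had a length). That correction kept the mean shift of each library, so it cannot decide whether length or GC bias was the source. The scaling of the TPM values cannot be told apart from a true excess of falls: with quantile normalization 50.5% of the called genes fell, but that step centres every library and so fixes the share near this value. An excess of falls caused by MTOAC stays open beside scaling and length or GC bias, as a hypothesis. For the count of genes, 10 splits are too few for a share under 0.05; the real split called 785, as many as 1 of the 10, and the highest other called 4, while for lists the real split called 7, as many as 5 of the 10, and the highest other called 9.

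Integrated stress response targets were higher with all 3 compounds by camera with the preset correlation, and were not called with an estimated correlation (adjusted p = 0.148, 0.121 and 0.105 for CPC, AEBDAC and MTOAC). The covariance of the fold changes of CPC and MTOAC over the list genes was 0.597, above the upper bound of 0.323 from simulated groups with no change. This argues against the shared vehicle libraries as the whole source of the differences between members that both compounds share. A covariance leaves out the list mean, so whether the shared vehicle libraries were the source of the higher list was not tested. Vehicle library 1 as that source is argued against by the list medians without it, the lowest of which kept 105% of its value. A response to quaternary ammonium compounds at these doses is a candidate explanation, as a hypothesis, and length or GC bias was not tested on this list.

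Of 100 assignments of the 12 libraries to 4 groups, 2 called as many genes in all 3 compounds as the 7 called in the real one. The highest other called 22, several times the real count. This may come from a structure of the libraries, and its cause was not tested. These assignments ignored the replicate numbers. Of 100 assignments within replicate numbers 1, the real one, called as many, and the highest other called 1, a share under 0.05. The share argues against random labels within numbers, where no compound has an effect. It does not test for an overlap beyond the shared vehicle libraries. The test was also chosen after the result was seen, so chance is not excluded for the overlap.

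For the other comparisons with vehicle 10 splits are likewise too few for a share under 0.05. With CPC the real split called 8 genes, as many as 1 of the 10, and the highest other called 1, or 0 among those that parted all 3 pairs; for lists it called 6, as many as 4 of the 10, and the highest other called 7, or 5 among those that parted all 3 pairs. With AEBDAC the real split called 153 genes, as many as 1 of the 10, and the highest other called 1. For lists it called 5, as many as 8 of the 10, and the highest other called 8. Among those that parted all 3 pairs the highest other called 1 gene and 6 lists, more lists than the real split. Over the 10 splits the number of lists called did not set the real split apart in any comparison with vehicle.

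Genes of the Y chromosome followed the replicate number and not the treatment. Eif2s3y was listed at 34.5 to 55.8 TPM in the libraries numbered 1 and 3 and at 0 in the library numbered 2 of all 4 groups, and Ddx3y likewise at 0 in those 4; Kdm5d stood at 10.9 to 16.3 TPM against 0.0927 to 0.269 TPM.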
